A study of Mus musculus with 15 samples.

How the data were processed

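The V4 region of the 16S rRNA gene was amplified from stool DNA and sequenced on an Illumina MiSeq. Per the labels, DNA was extracted with the QIAamp DNA Stool Mini Kit, 10 ng of template went through 25 PCR cycles with the NEBNext Q5 polymerase mix, and reads were 151 bases long. The deposited values are whole-number read counts per ASV, made by the authors before deposition with DADA2, known here only from the name of the deposited table. Its version, the read filters and the taxonomy database are not given in the sources used here. R 4.5.1 and limma are named per the submitters' processing notes, without their role.

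The table held 3697 ASVs, of which 3190 were at 0 in all 15 libraries. The 507 others carried 113 different taxonomy strings, merged into 109 genera or lowest named ranks, and were numbered by their total count. A genus was given for 270 ASVs, which held 65.3% of counts. There were 1403011 counts in all and 48847 to 197433 per library. ASVs of Eukaryota or without a phylum numbered 3 and held 0.00128% of counts; they stayed in the totals. Distances between libraries of one group lay between 0.163 and 0.742. Drawing both libraries of such a pair from their pooled counts, at their own depths, gave at most 0.0300.

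Groups followed the labels: arm (GPR15L or PBS) and time (before or after DSS). Library 7 entered no comparison because its title and the run of library names point to different times; the calls, named taxa, lists, diversity and distances were repeated with it as titled, and so was the number of ASVs found in 1 arm alone after DSS. The overlap of calls over DSS and the counts of other splits were not repeated with it. Titles name the mice as Gpr15 knockouts while the series text names Gpr15l, which was followed here. The labels list males where the design text speaks of both sexes, so sex was not analysed here. No paired analysis was possible because mouse numbers run from 1 to 15 with no number shared between the times. Cages were not analysed here, since the labels give no cage for any library.

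The 4 comparisons of 2 groups and the interaction were fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group, TMMwsp scaling, the quasi-likelihood fit in its default form and Benjamini-Hochberg adjustment at 0.05. The SE beside an edgeR log2 value was back-calculated as its absolute value over the square root of the test's F. It restates the test, and with a group at 0 it bounds nothing. ASVs, and counts summed per genus, were kept with at least 10 counts in all and at least 1 count in 3 or more libraries, which left 282 ASVs (99.0% of counts) and 78 genera. Bray-Curtis distances of relative abundances were tested by the pseudo-F, counting splits where it was at least as large. Shannon index (natural log), ASVs at equal depth (48847 counts) and taxon lists were tested two-sided by the difference in means. All these tests used exact permutation over every split. The smallest p these can give is 0.1 for 3 against 3 libraries and 0.0286 for 4 against 4 or 3 against 4. A list can therefore pass the adjustment only where 9 or more of the 15 lists reach that smallest p, and with 3 against 3 libraries none can. The 15 lists (Proteobacteria, Enterobacterales, facultative anaerobes, mucus-associated genera, Bacteroides with Parabacteroides, Muribaculaceae, Rikenellaceae with Prevotellaceae, butyrate-associated Clostridia, Lactobacillaceae with Bifidobacteriaceae, Erysipelotrichales with Turicibacter, Clostridiaceae with Peptostreptococcaceae, sulfate reducers, Helicobacteraceae with Campylobacterota, Gram-positive phyla, and sequences not bacterial or without a phylum) were tested as log2 of the summed percent plus 0.01, adjusted over the 15 lists. The comparisons, tests, lists, filters, the treatment of library 7 and most alternatives were fixed before the data were examined.

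Taxa named in the text are those past 0.05 with a mean share of at least 0.1% in 1 of the 2 groups: up to 10 genera and 5 ASVs each way by log2 fold change, all 15 lists and the 8 genera with the highest mean share. Where another taxon is named, the text says so.

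Alternatives were TMM, total counts as the only scaling, DESeq2 1.42.0 (poscounts), limma 3.58.1 voom, no count filter, a filter at a mean share of 0.1%, the 2 groups fitted alone, library 7 as titled, each library left out in turn, Aitchison (0.5 added), Jaccard and genus-sum distances, inverse Simpson index, ASV numbers without rarefaction or without ASVs under 10 counts, and pseudocounts of 0.1 and 0.001. In addition, 2 alternatives were chosen after the data were seen: edgeR's newer quasi-likelihood method and leaving out libraries 6 and 14 together.

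The tests were tested on simulated data. With the dispersions of the real counts (median 2.64 for ASVs and 1.45 for genera), a 16-fold change between the arms after DSS was recovered for 4.05% of ASVs and 21.8% of genera. Of the few ASV calls made there (0.9 per simulation), 11.1% were false. The false share was 14.3% over DSS in the GPR15L arm (0.35 calls per simulation) and 33.3% for the interaction (0.45). No taxon was planted as absent from a whole group. With a dispersion of 0.2, 99.2% of 16-fold and 79.2% of 4-fold changes of ASVs between the arms after DSS were recovered. There 4.17% of the calls were false. For the interaction 94.0% of 16-fold and 32.3% of 4-fold changes were recovered. The permutation test of a difference in means, with 4 against 4 values, gave p under 0.05 in 3.5% of simulations without a difference. With a shift of 4 SD it did so in 97.5%. For the distance test only the computed pseudo-F was checked on simulated counts, and its error rate and power were not simulated. Distances and tests of single values used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-bio 0.7.3, and figures matplotlib 3.10.9.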

Results

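Stool was collected from littermate mice lacking Gpr15l, the gene of a mucosal chemoattractant peptide that binds the receptor GPR15, before and after acute colitis caused by dextran sulfate sodium (DSS), a polysaccharide that injures the colonic epithelium. Recombinant human GPR15L or phosphate-buffered saline (PBS) was given by the rectal route each day, starting on day 3 and ending on day 9. The V4 region of the bacterial 16S rRNA gene was sequenced in 15 stool libraries, numbered 1 to 15 by their labels, and counts were given per amplicon sequence variant (ASV), a distinct amplicon sequence that stands for a strain or a group of close relatives. Before DSS there were 3 libraries of the GPR15L arm (1 to 3) and 3 of the PBS arm (4 to 6). After DSS there were 4 libraries of the GPR15L arm (8 to 11) and 4 of the PBS arm (12 to 15). Library 7 is titled as PBS after DSS, but its library name continues the run of names of the libraries taken before DSS, so it entered no comparison unless stated. Total counts ranged from 62726 to 197433 in the GPR15L arm before DSS, from 48847 to 162266 in the PBS arm before DSS, from 53417 to 144379 in the GPR15L arm after DSS and from 50041 to 67860 in the PBS arm after DSS. A count of 0 in all libraries of a group allows a share of up to 0.000912%, 0.000872%, 0.000912% and 0.00128% of counts in these 4 groups, in the same order, which covers counting error only. Folds against a group at 0 are therefore given as "at least", relative to 3 counts over that group's summed total.

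For the 14 libraries compared, the time point coincides with the run of library names, so a library batch cannot be told apart from the DSS course in comparisons over time. Rose and fell, said of a change over DSS, compare libraries before with libraries after and follow no mouse. The labels give 3 to 4 mice per cage and no cage for any library. Mice of a cage share gut bacteria, so p-values treat as independent mice that may have shared a cage, and cage and arm cannot be told apart. ASVs and genera were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 282 ASVs and 78 genera (or lowest named ranks).

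Muribaculaceae without a named genus, a family of mouse gut fermenters, made up 46.1% ± 16.9 (SD, n = 3) of counts in the GPR15L arm and 12.4% ± 1.78 (n = 3) in the PBS arm before DSS, and 21.5% ± 7.23 (n = 4) and 17.3% ± 6.44 (n = 4) after DSS. Bacteroides made up 16.4% ± 13.2 and 16.8% ± 10.1 before DSS and 27.8% ± 11.2 and 23.7% ± 11.4 after DSS, in the GPR15L and PBS arms. Helicobacter stood at 7.48% ± 4.35 and 13.9% ± 8.56 before and at 10.0% ± 4.36 and 10.0% ± 2.30 after DSS. Mucispirillum, a mucus-layer bacterium, stood at 1.06% ± 1.03 and 8.54% ± 13.6 before and at 7.43% ± 5.97 and 4.20% ± 1.12 after DSS. Turicimonas stood at 8.43% ± 2.30 and 6.51% ± 5.11 before and at 2.66% ± 2.58 and 0.640% ± 0.411 after DSS. The Lachnospiraceae NK4A136 group, Lachnospiraceae without a genus and Prevotellaceae UCG-001 were at most 9.24% ± 5.95, 8.78% ± 4.16 and 4.01% ± 2.33 in any group. Some of these means rest on 1 library. Mucispirillum before DSS was at 0.707% in the PBS arm without library 6, below the mean of the GPR15L arm, which was 0.495% without library 1, and it was at 4.83% after DSS in the GPR15L arm without library 9. Bacteroides was at 9.00% without library 1, Helicobacter at 8.97% without library 6, and Turicimonas at 3.97% without library 5 and at 1.38% without library 10. None of these 8 genera, those with the highest mean share, passed the edgeR threshold in any of the 5 comparisons.

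**Figure D1:**
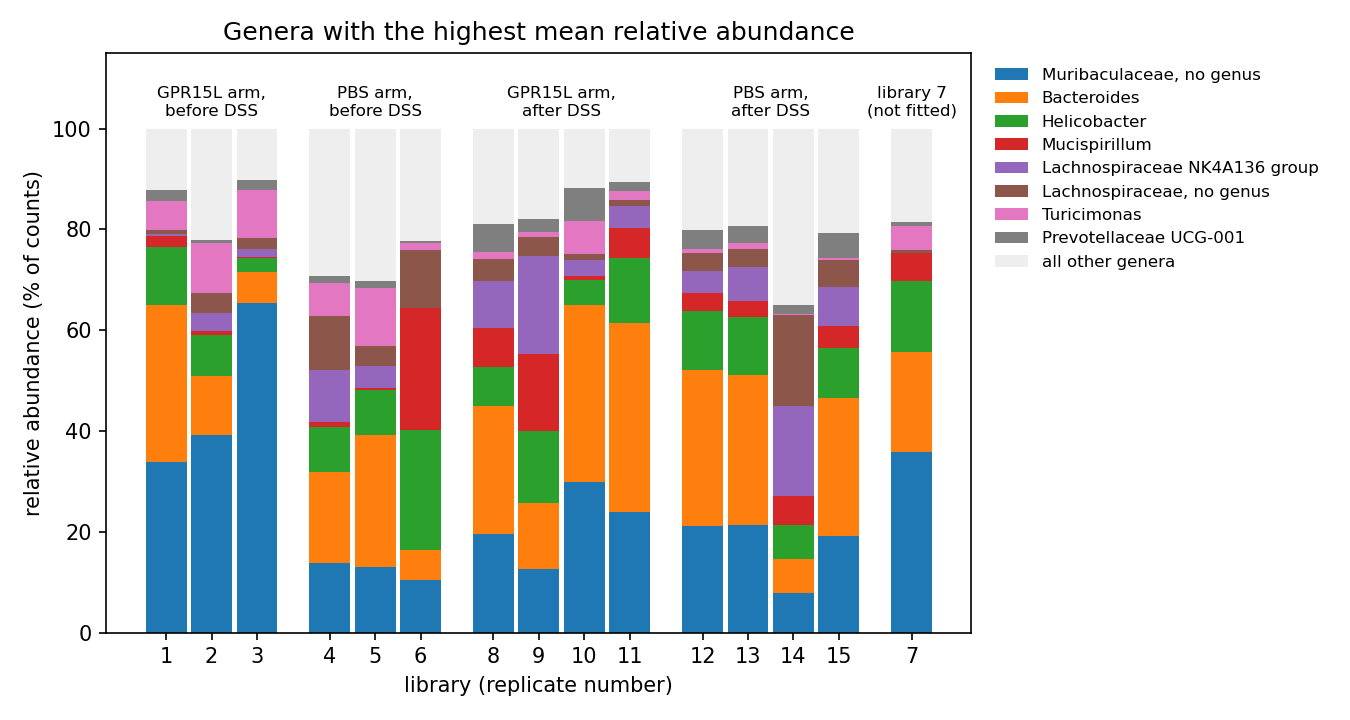
Relative abundance (% of counts, vertical axis) of the 8 genera or lowest named ranks with the highest mean share, as stacked bars for each of the 15 libraries (horizontal axis, replicate numbers) by group. Muribaculaceae without a genus were at or above 33.8% in the 3 libraries of the GPR15L arm before DSS and at or below 13.7% in the 3 of the PBS arm before DSS.

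The arms were first compared before DSS. Whether these were the mice or cages compared after DSS is not known, so this may not be the starting difference of those. The 4 ASVs that were higher in the GPR15L arm were all Muribaculaceae without a genus and had no count in the PBS arm. ASV49 made up 1.59% ± 0.557 (n = 3) of counts in the GPR15L arm and was at least 1820-fold higher (edgeR adjusted p = 0.0240), and ASV114 made up 0.325% ± 0.203 and was at least 373-fold higher (adjusted p = 0.0240). ASV75 and ASV82 were at least 884-fold and 785-fold higher (edgeR adjusted p = 0.0467 for each). The ASV that was lower in the GPR15L arm, ASV63 of the Clostridia vadinBB60 group, was at 0 there and at 0.0286% ± 0.0196 (0.0177% without library 4) in the PBS arm (edgeR adjusted p = 0.0240); this ASV was chosen after its values were seen.

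Across the 42 tested Muribaculaceae ASVs, 4 were higher, 0 lower and 38 did not pass, both over all ASVs and adjusted over the list alone. The family as a whole made up 47.1% ± 17.1 in the GPR15L arm and 12.8% ± 1.86 in the PBS arm, with no overlap between libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give, adjusted over 15 lists 0.5). Gram-positive phyla made up 12.8% ± 9.32 and 30.5% ± 6.52 (exact permutation p = 0.1, n = 3 each, adjusted 0.5), and 7.53% in the GPR15L arm without library 2. None of the 15 taxon lists could pass the adjustment with 3 against 3 libraries.

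In all, 5 of 282 ASVs (50 at unadjusted p under 0.05) and 0 of 78 genera (13 at unadjusted p under 0.05, 4 by DESeq2 and 4 by limma voom) passed before DSS. Bray-Curtis distance gave an R2 of 0.298 between the arms (exact permutation p = 0.1, n = 3 each). This is the smallest p that 3 against 3 libraries can give, so the test could not decide whether the arms lay apart. Shannon index was 3.87 ± 0.24 against 3.69 ± 0.83 (exact permutation p = 0.7), a difference that turned to -0.234 without library 6. ASVs at equal depth were 183 ± 17.5 and between 90.6 and 295 (exact permutation p = 0.9, n = 3 each), and the sign of the difference turned without library 3 (5.80) or 4 (49.8). The count of 5 ASVs fell to 0 without library 1, 2, 3 or 5, to 1 without library 4 and to 0 with library 7 as titled. It was 3 with total counts as the only scaling, 3 with the 2 groups fitted alone, 10 without the count filter, 13 with DESeq2 (8 higher, 5 lower) and 11 with limma voom. ASV75 and ASV82 lost their calls with total counts (edgeR adjusted p = 0.0594 for each) and ASV114 with the 2 groups fitted alone (0.135). The median log2 fold change of all genera was -0.54, -0.49 with TMM and -1.13 with total counts as the only scaling, and that of all ASVs -0.37, -0.43 and -0.49. In the PBS arm, library 6 lay apart from libraries 4 and 5, with 90.6 ASVs at equal depth against 295 and 175.

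After DSS the arms differed, among the libraries compared, in which bacteria were detected at all. This is the comparison the series was made for, rectal GPR15L against placebo in colitis. ASVs found in every library of 1 arm and in none of the other numbered 18 for GPR15L and 41 for PBS. With library 7 as titled they numbered 11 and 0. Akkermansia, a mucin-degrading genus, made up 0.312% ± 0.284 (n = 4) of counts in the GPR15L arm and had no count in the PBS arm (n = 4), at least 243-fold higher (edgeR adjusted p = 0.0115); without library 10 its mean was 0.176%. Parasutterella, a commensal of the Proteobacteria, made up 0.623% ± 0.362 and had no count in the PBS arm, at least 485-fold higher (edgeR adjusted p = 0.0201). Library 7, titled as PBS after DSS, held it at 0.485%, and with that library as titled it did not pass (0.304). The [Eubacterium] siraeum group and UCG-009, both members of the Clostridia, had no count in the GPR15L arm and made up 0.544% ± 0.131 and 0.291% ± 0.149 in the PBS arm, at least 597-fold and 319-fold lower with GPR15L (edgeR adjusted p = 0.00287 and 0.00756). The Clostridia vadinBB60 group made up 0.772% ± 0.409 with GPR15L and 7.87% ± 2.39 with PBS (log2 fold change -3.48 ± 0.92 SE, edgeR adjusted p = 0.0201), and Anaerotruncus 0.691% ± 0.488 and 0.0811% ± 0.0165 (2.87 ± 0.79 SE, adjusted p = 0.0211).

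**Figure D2:**
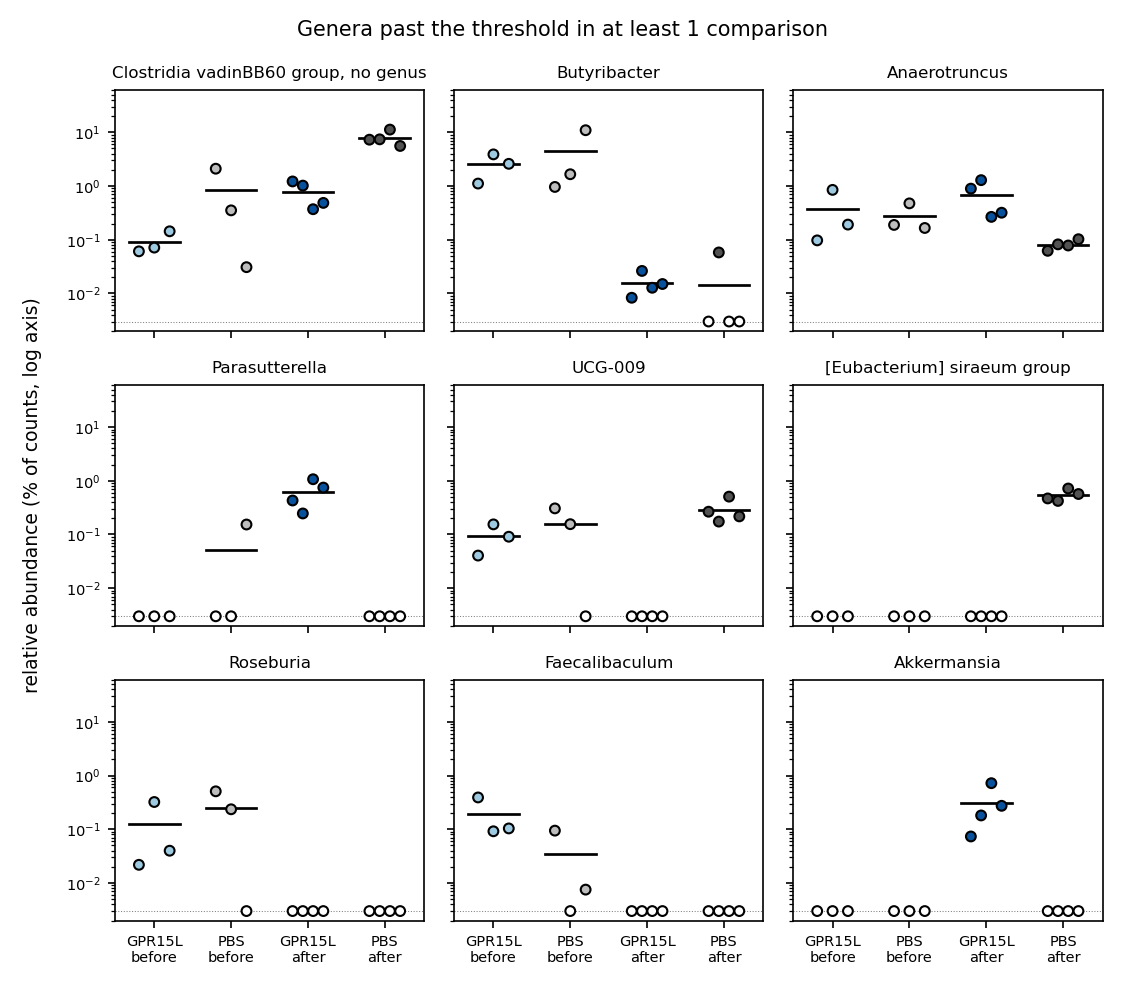
Relative abundance (% of counts, log axis) per library of the 9 named genera that passed the edgeR threshold in at least 1 comparison, by arm and time (GPR15L arm in blue, PBS arm in grey). Points are libraries (3 per group before and 4 after DSS), bars are group means, and open points on the dotted line are libraries with a count of 0. Parasutterella and Akkermansia lay on the dotted line in the 4 PBS libraries after DSS, and the [Eubacterium] siraeum group in the 4 GPR15L libraries.

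At the level of ASVs, Bacteroides held changes that its total did not show. Its total did not pass the test (log2 fold change 0.43 ± 0.78 SE, edgeR adjusted p = 0.865). ASV4 and ASV10, which made up 3.73% ± 1.66 and 2.29% ± 1.16 in the GPR15L arm, had no count in the PBS arm and were at least 2905-fold and 1783-fold higher with GPR15L (edgeR adjusted p = 3.51e-05 and 4.04e-05), while ASV29 made up 0.0139% ± 0.0171 with GPR15L and 5.62% ± 2.85 with PBS (log2 fold change -8.15 ± 1.91 SE, adjusted p = 0.0141). ASV29 was chosen for this comparison after its values were seen. Library 7, titled as PBS after DSS, held ASV4 at 5.73%, ASV10 at 2.94%, ASV96 at 0.358% and ASV29 at 0. When it was counted as titled, ASV4, ASV10 and ASV96 did not pass (edgeR adjusted p = 0.517, 0.423 and 0.382). Muribaculaceae without a genus had 1 ASV higher and 9 lower of 41 tested, among them ASV44 and ASV50, which were at 0 with GPR15L and at 1.23% ± 0.715 and 0.662% ± 0.298 with PBS (at least 1352-fold and 727-fold lower, edgeR adjusted p = 0.00426 for each). In the Clostridia vadinBB60 group 10 of 13 ASVs were lower and none higher. The Lachnospiraceae NK4A136 group had 5 ASVs higher and 3 lower of 29, and Lachnospiraceae without a genus 4 higher and 6 lower of 40. ASV41, ASV58 and ASV103 of these Lachnospiraceae were at 0 with GPR15L and made up 2.98% ± 4.52, 1.23% ± 1.17 and 0.721% ± 0.624 with PBS, but 0.735%, 0.664% and 0.428% without library 14. All 3 Parasutterella ASVs were higher, among them ASV96 (0.448% ± 0.250), as were ASV99 of the Oscillospiraceae (0.421% ± 0.415) and the 1 Akkermansia ASV, ASV140, and ASV96, ASV99 and ASV140 had no count with PBS. Without library 8 the mean of ASV99 was 0.246%, and without library 10 that of ASV29 with GPR15L was 0.00686%.

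**Figure D3:**
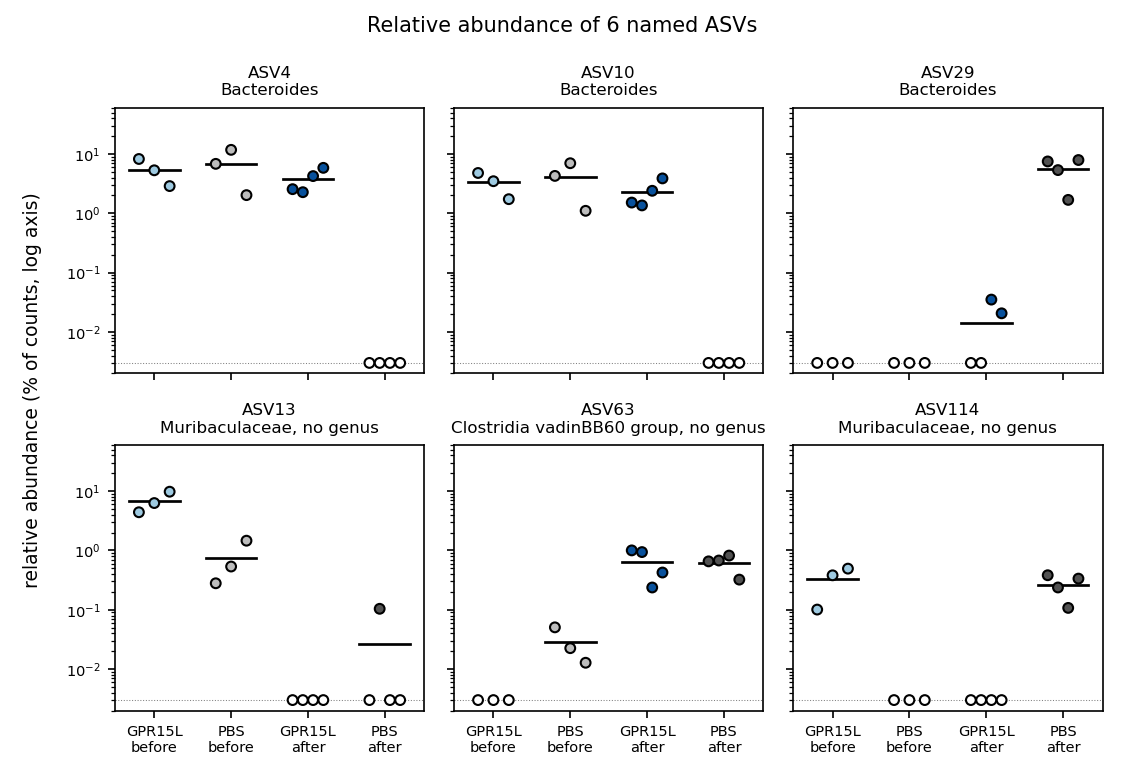
Relative abundance (% of counts, log axis) per library of 6 ASVs, with the genus or lowest rank in each title, by arm and time (GPR15L arm in blue, PBS arm in grey). Points are libraries (3 per group before and 4 after DSS), bars are group means, and open points on the dotted line are libraries with a count of 0. ASV4 and ASV10 were at 0 in the 4 PBS libraries after DSS, where ASV29 lay between 1.69% and 7.93%.

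Of the 15 taxon lists, none passed the adjustment after DSS. Their smallest p was 0.0286, the lowest that 4 against 4 libraries can give by the two-sided exact permutation test, and 0.143 when adjusted, for 3 lists. Proteobacteria made up 3.46% ± 2.94 with GPR15L and 0.714% ± 0.391 with PBS, with 4 of 9 ASVs higher. Erysipelotrichales and Turicibacter made up 0.0346% ± 0.00757 and 0.121% ± 0.0301, with 0 of 6 ASVs past the threshold. Clostridiaceae and Peptostreptococcaceae made up 0.00598% ± 0.0120 and 0.253% ± 0.145, with 1 of 3 ASVs lower, and 2 lower when adjusted over the list alone. The unadjusted exact permutation p with library 7 as titled was 0.143 for Proteobacteria and 0.389 for Erysipelotrichales and Turicibacter. For Clostridiaceae and Peptostreptococcaceae it was 0.00794. Their share in library 7 was mostly Clostridioides (5.23%), at 0 in libraries 12 to 15 and picked after its values were seen. The unadjusted exact permutation p was 0.0571 for Proteobacteria without library 10, 11, 12, 14 or 15. For the other 12 lists the adjusted p of this exact permutation test lay between 0.536 and 1. Butyrate-associated Clostridia, the families of most butyrate producers, made up 18.3% ± 12.3 and 24.8% ± 17.7, with 20 ASVs higher and 27 lower of 159 (22 and 30 adjusted over the list alone). Gram-positive phyla made up 20.2% ± 12.8 with GPR15L and between 23.4% and 63.4% in the 4 libraries with PBS, with 20 higher and 39 lower of 194 (24 and 45 adjusted over the list alone). Muribaculaceae with named genera included made up 22.9% ± 7.57 and 17.7% ± 6.26, with 2 higher and 9 lower of 42. Bacteroides with Parabacteroides made up 28.3% ± 11.4 and 24.4% ± 11.7, with 2 higher and 1 lower of 11. Akkermansia with Mucispirillum, the mucus-associated genera, made up 7.74% ± 5.76 and 4.20% ± 1.12, with 1 of 3 higher. Helicobacteraceae and Campylobacterota made up 10.0% ± 4.36 and 10.0% ± 2.30, with 1 of 4 higher. For these 4 lists the numbers were the same when adjusted over the list alone. Rikenellaceae and Prevotellaceae (4.75% ± 2.55 and 5.46% ± 1.76), sulfate reducers (0.595% ± 0.305 and 0.517% ± 0.221) and Lactobacillaceae and Bifidobacteriaceae (0.148% ± 0.0380 and 0.310% ± 0.140) had no ASV past the threshold. Enterobacterales (0.00362% ± 0.00464 and 0), facultative anaerobes (0.00362% ± 0.00464 and 0.00899% ± 0.0180) and sequences that were not bacterial or had no phylum, mostly mitochondria (0.471% ± 0.198 and 0.310% ± 0.276), also had none. With library 7 as titled, the differences of Enterobacterales, Rikenellaceae and Prevotellaceae, butyrate-associated Clostridia and sulfate reducers turned sign (log2 -0.06, 0.12, 0.22 and -0.11). The sign also turned for Bacteroides with Parabacteroides without library 14 (-0.20), for Helicobacteraceae and Campylobacterota without library 10 (0.20), for facultative anaerobes without library 13 (0.39) and for sulfate reducers without library 9, 13 or 15 (-0.13, -0.031 and -0.033). Without library 10 the share with GPR15L was 2.02% for Proteobacteria and 0 for Clostridiaceae and Peptostreptococcaceae, and without library 8 it was 0.00159% for Enterobacterales and for facultative anaerobes. Without library 14 the share with PBS was 16.1% for butyrate-associated Clostridia and 0.172% for sequences that were not bacterial, and without library 13 it was 0 for facultative anaerobes.

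In all, 79 of 282 ASVs (30 higher and 49 lower with GPR15L) and 11 of 78 genera (3 higher, 8 lower; 7 and 8 with DESeq2) passed after DSS. The genera under 0.1% of counts among these 11 were Christensenellaceae, Ruminococcus, Lachnospiraceae UCG-010, Candidatus Saccharimonas and Candidatus Arthromitus, a genus of segmented filamentous bacteria, each lower and at 0 with GPR15L; they were named after their values were seen. Bray-Curtis distance gave an R2 of 0.440 between the arms (pseudo-F 4.71, exact permutation p = 0.0286, n = 4 each), and 0.201 (exact permutation p = 0.257) when computed on genus sums. Shannon index was 3.61 ± 0.24 and 3.87 ± 0.19 (exact permutation p = 0.229), and ASVs at equal depth 152 ± 21.4 and 178 ± 5.51 (exact permutation p = 0.0857, n = 4 each), which became -34.9 ASVs and past the threshold without library 8, and -8.62 ASVs with library 7 as titled. Counting library 7 as titled left 3 genera and ended the calls of the vadinBB60 group, Anaerotruncus, Parasutterella, ASV4, ASV10 and ASV96 (edgeR adjusted p = 0.191, 0.0655, 0.304, 0.517, 0.423 and 0.382). Genera past the threshold numbered 3 without library 8, 4 without library 9 and 6 without library 14, and they became 6 with a filter at 0.1% of counts and 18 with the 2 groups fitted alone. ASVs numbered 52 without library 8 and 48 with that filter. The 30 higher ASVs became 15 without library 14 or 15, 17 without library 12, 18 without library 8 or 13, 20 without library 9, 13 with that filter and 52 with the 2 groups fitted alone. Parasutterella missed it without library 8 or 14 (0.0535 and 0.0609), the vadinBB60 group without 8, 9 or 14 (0.0516 to 0.0565) and Anaerotruncus without 8, 9, 12, 13, 14 or 15 (0.0537 to 0.0716).

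**Figure D4:**
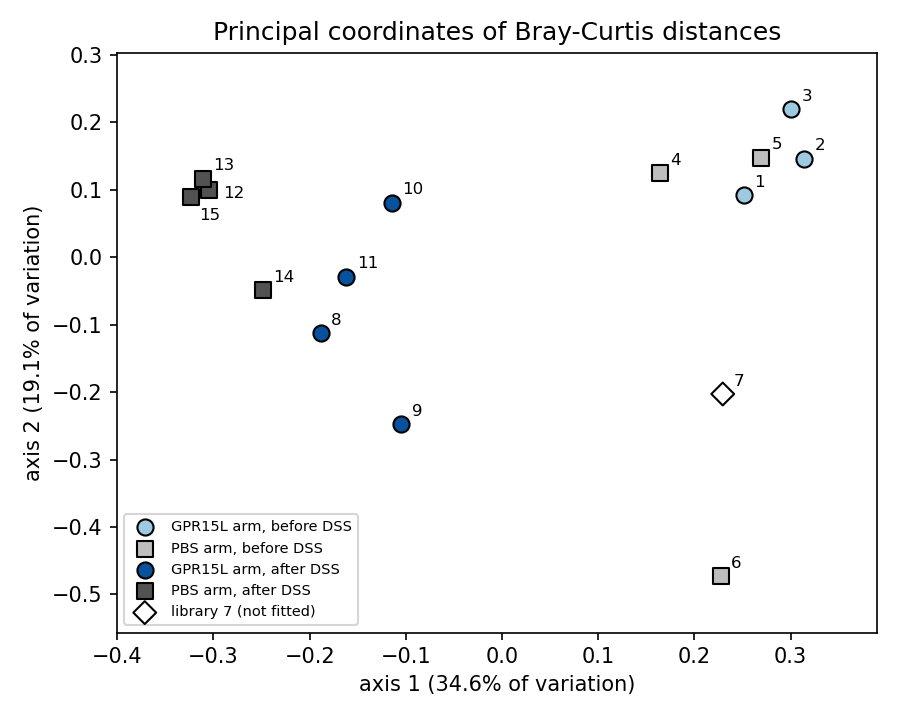
Principal coordinates of Bray-Curtis distances between the 15 libraries (numbers are replicate numbers), with axis 1 (34.6% of the variation) and axis 2 (19.1%) as the horizontal and vertical axes. Circles are the GPR15L arm, squares the PBS arm, light symbols before and dark symbols after DSS, and the open diamond is library 7. The 8 libraries after DSS lay at negative values of axis 1 and the 6 before DSS at positive values, as did library 7.

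In the PBS arm, Bacteroides ASVs differed between the 3 libraries before and the 4 after DSS, a difference that library 7 did not share. ASV4 and ASV10 made up 6.88% ± 4.87 and 4.13% ± 2.95 before DSS (n = 3) and had no count after it (n = 4), at least 5354-fold and 3213-fold lower (edgeR adjusted p = 2.96e-05 and 3.47e-05). ASV29 had no count before DSS and made up 5.62% ± 2.85 after it, at least 6445-fold higher (edgeR adjusted p = 0.00935). Library 7, titled as PBS after DSS, held ASV4 at 5.73%, ASV10 at 2.94% and ASV29 at 0. When it was counted as titled, ASV4 and ASV10 did not pass (edgeR adjusted p = 0.505 and 0.469), while ASV29 did (0.0493). Among genera, the [Eubacterium] siraeum group rose from 0 to 0.544% ± 0.131 (at least 624-fold, edgeR adjusted p = 0.00611), the Clostridia vadinBB60 group rose from 0.828% ± 1.11 to 7.87% ± 2.39 (log2 fold change 3.86 ± 1.05 SE, adjusted p = 0.0437), and Butyribacter, a genus of butyrate-forming Lachnospiraceae, fell from 4.52% ± 5.57 to 0.0145% ± 0.0290 (-8.05 ± 1.88 SE, edgeR adjusted p = 0.0245). Before DSS the mean was 0.191% for the vadinBB60 group without library 4, 1.31% for Butyribacter without library 6, and 4.43% and 2.69% for ASV4 and ASV10 without library 5. After DSS Butyribacter had counts in library 13 alone.

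Other named ASVs moved both ways in the PBS arm. ASV63 of the vadinBB60 group rose (log2 fold change 4.44 ± 1.13 SE, edgeR adjusted p = 0.0397), ASV103 of the Lachnospiraceae rose (8.72 ± 2.12 SE, adjusted p = 0.0404), and ASV114 of the Muribaculaceae and ASV119 of the siraeum group rose from 0 to 0.266% ± 0.121 and 0.544% ± 0.131 (adjusted p = 0.0115 and 0.0151). ASV34 of Turicimonas fell from 1.62% ± 1.04 to 0.00295% ± 0.00589 (-9.29 ± 1.69 SE, edgeR adjusted p = 0.00271), where only library 14 had counts of it. The Muribaculaceae ASV15 and ASV57 fell from 0.856% ± 1.16 (0.184% without library 6) and 0.350% ± 0.307 to 0 (edgeR adjusted p = 0.00134 and 0.0397). Of the 42 Muribaculaceae ASVs 1 rose, 2 fell (3 adjusted over the list alone) and 39 did not pass, and of the 11 of Bacteroides and Parabacteroides 1 rose (2 adjusted over the list alone), 2 fell and 8 did not pass. Proteobacteria made up 6.92% ± 4.84 (4.56% without library 5) before and 0.714% ± 0.391 after DSS (exact permutation p = 0.0286, n = 3 and 4, adjusted 0.429), with 1 of 9 ASVs lower (4 adjusted over the list alone). None of the 15 lists passed.

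In the PBS arm, 12 ASVs (5 higher, 7 lower; 89 at unadjusted p under 0.05) and 4 genera (3 higher, 1 lower) passed, the remaining genus being Ruminococcus at 0.0889% ± 0.0391 after DSS, named after its values were seen. Bray-Curtis distance gave an R2 of 0.482 (exact permutation p = 0.0286, n = 4 and 3), 0.263 on genus sums (exact permutation p = 0.114) and 0.299 with library 7 as titled (exact permutation p = 0.0893). Shannon index was 3.87 ± 0.19 after and 3.69 ± 0.83 before DSS, and ASVs at equal depth 178 ± 5.51 after and between 90.6 and 295 before (exact permutation p = 0.686 and 0.8, n = 4 and 3). These differences turned sign without library 6 (-0.231) and without library 4 (45.6). These calls depended on the setting. The 12 ASVs became 47 with DESeq2, 56 with limma voom, 36 without the count filter, 53 with edgeR's newer quasi-likelihood method and 7 without library 12. The 5 higher ASVs became 2 without library 12 or 15 and 3 without library 5 or 14, the 7 lower 12 without library 4 or 13, and the 4 genera became 13, 12, 4 and 17 with the first 4 of these. When libraries were left out in turn, 9 genera passed without library 4, 7 without 6, 2 without 5, 12 or 13 and 1 without 14 or 15. They numbered 2 with a filter at 0.1% of counts, 2 with the 2 groups fitted alone and 2 without libraries 6 and 14. With library 7 as titled 3 ASVs and 1 genus passed, and ASV4, ASV10, ASV34, ASV114, ASV119, ASV63, ASV103 and the siraeum and vadinBB60 groups did not (edgeR adjusted p = 0.505, 0.469, 0.480, 0.0896, 0.0896, 0.195, 0.0919, 0.0774 and 0.215), while ASV15 turned to 0.72. The vadinBB60 group kept its call only without library 4 or 6 among the 7 left out in turn, and Butyribacter lost its own without 14 or 15 (0.0933 and 0.0535), and both missed the threshold with the 2 groups fitted alone (0.109 for each). ASV63 lost its call without library 4, 5, 12, 13, 14 or 15 (0.0586 to 0.108), ASV103 without 4, 5, 12, 14 or 15 (0.0517 to 0.108), ASV57 without 5, 12, 14 or 15 (0.0798 to 0.103) and ASV119 without 12 or 15 (0.0586 and 0.0571). The vadinBB60 group also missed it with total counts (0.0784) and with a filter at 0.1% of counts (0.0538), ASV63 with TMM (0.0568), total counts (0.0517), no filter (0.0904) and the 2 groups alone (0.0563), and ASV103 with total counts (0.0517). Without libraries 6 and 14, the vadinBB60 group, Butyribacter, ASV63 and ASV103 missed it (0.0746, 0.0746, 0.0529 and 0.108). With total counts as the only scaling 1 genus rose and 2 fell, 3 ASVs rose and 7 fell, with TMM 4 ASVs rose and 10 fell, and with DESeq2 6 genera rose and 7 fell. The median log2 fold change of all genera was -0.56, -0.99 with TMM and -0.75 with total counts.

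In the GPR15L arm, 22 of 42 Muribaculaceae ASVs fell over the DSS course, 1 rose and 19 did not pass, with the same numbers adjusted over the list alone. The family as a whole, at 47.1% ± 17.1 before and 22.9% ± 7.57 after DSS, did not pass (two-sided exact permutation p = 0.0571, n = 3 and 4, adjusted over 15 lists 0.257). Bacteroides ASV4 and ASV10 did not change past the threshold. ASV13 fell from 6.84% ± 2.73 (n = 3) to 0 (n = 4), at least 7507-fold (edgeR adjusted p = 0.00870), and ASV37, ASV49, ASV57 and ASV61 fell from 2.67% ± 0.833, 1.59% ± 0.557, 1.46% ± 1.17 and 1.55% ± 1.27 (0.816% and 0.836% for the last 2 without library 3) to 0 (adjusted p = 0.00965, 0.00712, 0.0101 and 0.0125). ASV4 was at 5.48% ± 2.69 and 3.73% ± 1.66 and ASV10 at 3.34% ± 1.53 and 2.29% ± 1.16, before and after DSS (edgeR adjusted p = 0.749 and 0.774). Parasutterella rose from 0 to 0.623% ± 0.362 and Akkermansia from 0 to 0.312% ± 0.284 (0.176% without library 10), at least 683-fold and 342-fold (edgeR adjusted p = 0.0395 and 0.0217). Both calls were lost when any single library of this arm was left out.

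Butyribacter fell in this arm too, from 2.53% ± 1.39 to 0.0156% ± 0.00763 (log2 fold change -7.83 ± 1.86 SE, edgeR adjusted p = 0.0217). Faecalibaculum, of the Erysipelotrichaceae, and Roseburia, a butyrate producer, fell from 0.195% ± 0.169 (0.0977% without library 1) and 0.128% ± 0.168 (0.0308% without library 2) to 0, at least 214-fold and 140-fold (edgeR adjusted p = 0.0217 and 0.0395). ASV63 of the vadinBB60 group rose from 0 to 0.652% ± 0.379 (at least 714-fold, edgeR adjusted p = 0.000914), and ASV39, ASV73 and ASV74 of the Lachnospiraceae NK4A136 group rose from 0 to 1.87% ± 2.13, 0.972% ± 0.665 and a mean of 0.723% (0 to 1.80%) (adjusted p = 0.0285, 0.0329 and 0.0288), with ASV39 and ASV74 found in part of the libraries after DSS and at 0.969% and 0.363% without library 9. ASV96 of Parasutterella rose from 0 to 0.448% ± 0.250 (edgeR adjusted p = 0.0349). Of the 159 ASVs of butyrate-associated Clostridia 17 rose, 23 fell (8 and 11 adjusted over the list alone) and 119 did not pass, and of the 6 of Erysipelotrichales and Turicibacter 2 fell (2 rose and 2 fell adjusted over the list alone). The list of Erysipelotrichales and Turicibacter made up 0.605% ± 0.358 before and 0.0346% ± 0.00757 after DSS, and sequences that were not bacterial or had no phylum 0.0289% ± 0.0272 (0.0157% without library 2) and 0.471% ± 0.198 (exact permutation p = 0.0286, n = 3 and 4, adjusted 0.214, for each). None of the 15 lists passed.

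In the GPR15L arm, 80 ASVs (25 higher, 55 lower) and 8 genera (2 higher, 6 lower) passed, and UCG-009, Rikenella and Lachnospiraceae UCG-010, under 0.1% of counts and named after their values were seen, were the remaining genera, each at 0 after DSS. Bray-Curtis distance gave an R2 of 0.563 (exact permutation p = 0.0286, n = 4 and 3), and 0.415 on genus sums (exact permutation p = 0.0571). Shannon index was 3.61 ± 0.24 after and 3.87 ± 0.24 before DSS, and ASVs at equal depth 152 ± 21.4 and 183 ± 17.5 (exact permutation p = 0.286 and 0.114, n = 4 and 3). With 1 library fewer, the ASVs past the threshold fell to between 21 (without library 9) and 32 (without library 11), being 31, 30 and 22 without library 1, 2 or 3 and 22 and 30 without library 8 or 10. The 25 higher ASVs fell to 5, 1 and 2 without library 1, 2 or 3 and to 3, 2, 3 and 9 without library 8, 9, 10 or 11, and the 55 lower to between 19 and 29. The 8 genera fell to 0 without library 3, 8, 9, 10 or 11, to 2 without library 1 and to 3 without library 2. Parasutterella, Akkermansia, Roseburia, ASV73 and ASV96 each lost the call without any one of the 7 libraries (edgeR adjusted p = 0.0503 to 0.106), ASV39 and ASV74 without any but library 11 (0.0511 to 0.0743), Faecalibaculum without any but library 2 (0.0528 to 0.0892) and Butyribacter without library 3, 8, 9, 10 or 11 (0.0556 to 0.0892). With library 7 as titled, which shares the estimate of the spread, 36 ASVs and 4 genera passed, and Parasutterella, Roseburia and ASV96 did not (edgeR adjusted p = 0.0943, 0.0701 and 0.0610). The 8 genera became 14 with DESeq2, with limma voom and without libraries 6 and 14, 15 with the newer quasi-likelihood method and 18 with the 2 groups fitted alone, and with total counts as the only scaling 3 rose and 5 fell, against 6 and 8 with DESeq2. The median log2 fold change was 0 for all ASVs (-0.20 with TMM) and 0 for all genera (0.24 with total counts).

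The change over DSS was then compared between the arms by an interaction term. Parasutterella changed more upward in the GPR15L arm (difference of log2 fold changes 21.18 ± 4.37 SE, edgeR adjusted p = 0.0247), UCG-009 more downward (-11.22 ± 2.57 SE, adjusted p = 0.0247), as did Candidatus Arthromitus, under 0.1% of counts and named after its values were seen (-13.41). These fitted values and their SE involve groups at 0, depend on the prior count and bound nothing. Bacteroides ASV4 and ASV10 differed by 14.98 ± 1.73 SE and 14.26 ± 1.78 SE (edgeR adjusted p = 0.000271 and 0.000310), as both were at 0 in libraries 12 to 15. Neither passed with library 7 as titled (edgeR adjusted p = 0.909 and 0.832). Parasutterella ASV96 and ASV151 and Oscillospiraceae ASV99 had differences of 20.54, 17.87 and 17.26 (edgeR adjusted p = 0.0161, 0.0406 and 0.0165).

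Of 41 tested Muribaculaceae ASVs without a genus, 9 changed more downward in the GPR15L arm, 1 more upward and 31 did not pass. ASV114 had the most negative value, -21.94 ± 2.90 SE (edgeR adjusted p = 0.00107). It was at 0.325% ± 0.203 before and 0 after DSS in the GPR15L arm, and at 0 before and 0.266% ± 0.121 after DSS in the PBS arm. The labels share no mouse number between the times and give no cage. Whether an arm held the same mice or cages at both times is therefore not known. ASV97, ASV110, ASV89 and ASV44 had differences of -19.15, -16.71, -15.23 and -14.87 (edgeR adjusted p = 0.0345, 0.00802, 0.00802 and 0.00802). ASV29, at 0 in both arms before DSS, had no estimable difference.

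The interaction passed for 28 ASVs (10 higher, 18 lower) and 3 genera (1 higher, 2 lower). Library 6 was the single library of the PBS arm with Parasutterella before DSS (0.153%), and also with ASV96, ASV99 and ASV151. Without it, these taxa were at 0 in all groups but the GPR15L arm after DSS. Their differences were then not estimable, so the loss of their calls was fixed in advance. With library 7 as titled 9 ASVs and 0 genera passed, and ASV4, ASV10, ASV96, ASV151, Parasutterella and UCG-009 did not (edgeR adjusted p = 0.909, 0.832, 0.124, 0.151, 0.212 and 0.163). The 3 genera became 0 without library 1, 3, 8 or 14, 1 without library 5 or 6 and 7 without library 4, and 11 (5 higher, 6 lower), 12 and 6 with DESeq2, limma voom and the newer quasi-likelihood method. The 10 higher ASVs became 19 without library 4 and the 18 lower 9 without library 5. The 28 ASVs became 17 without library 5, 52 with DESeq2, 82 with limma voom and 43 without the count filter. ASV97 lost its call without library 4, 5, 6, 8, 10 or 12 (edgeR adjusted p = 0.0512 to 0.0747), and ASV151 without library 1, 2, 3, 5, 8, 10, 11, 12 or 14 (0.0503 to 0.0813). Parasutterella and UCG-009 lost theirs without library 1, 3, 8 or 14 (edgeR adjusted p = 0.0539 to 0.0695), and UCG-009 also without library 5 (0.0623). The median over all ASVs was 0.33 (0.02 with TMM, 0.17 with total counts) and over all genera 0.48 (0.67 and 0.96).

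Calls over the DSS course were set side by side between the arms, which share no library. Both lists come from the same fit and filter, and in both arms time coincides with the run of library names. The numbers for independent lists are therefore no measure of chance. Butyribacter was the genus lower in both, where independent lists would share 0.0769. ASV29 and ASV63 were higher in both (2 of 5 in the PBS arm and of 25 in the GPR15L arm, where independent lists would share 0.443), and ASV21, named after its values were seen, and ASV57 were lower in both (2 of 7 and of 55, where independent lists would share 1.37).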

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

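The counts of other splits, the depth tests of libraries 6 and 7, the tests of arm differences in place before DSS and the test of library 6 against the GPR15L arm were chosen after the result was seen.

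A gap test for a library far from the other 3 of its group was run on 61 values, and chance gives about 1 in 20 groups; 12 values passed. Library 14 (PBS after DSS) gave 7 of them: Bacteroides and Parabacteroides 6.97% (others 28.3% to 31.8%), Bacteroides alone 6.82%, the Muribaculaceae list 8.36% (19.7% to 21.3%), Muribaculaceae without a genus 7.78%, Gram-positive phyla 63.4% (23.4% to 28.0%), Lachnospiraceae without a genus 17.9% (3.54% to 5.44%) and sequences not bacterial or without a phylum 0.724% (0.160% to 0.190%). These shares are parts of the same whole and overlap, so they are not 7 separate observations. The others were library 8 with 144379 counts (others 53417 to 68606), Turicimonas at 6.49% (0.997% to 1.85%) in library 10, Clostridiaceae and Peptostreptococcaceae at 0.0239% (others 0) in library 10, and facultative anaerobes at 0.0360% and Butyribacter at 0.0580% (others 0 for each) in library 13. For the last 3, with the others at 0, any value above 0 passes this test, so they say nothing about a library apart and the chance rate does not apply to them.

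The change over DSS differed between the arms by the edgeR interaction for Parasutterella (21.18), UCG-009 (-11.22), Parasutterella ASV96 (20.54) and ASV151 (17.87), Oscillospiraceae ASV99 (17.26), Bacteroides ASV4 (14.98) and ASV10 (14.26), and Muribaculaceae ASV114 (-21.94), ASV97 (-19.15), ASV110 (-16.71), ASV89 (-15.23) and ASV44 (-14.87), in log2 units that depend on the prior count. Without library 6, Parasutterella, ASV96, ASV99 and ASV151 had no estimable difference. Each was then at 0 in all groups but the GPR15L arm after DSS. Neither genus passed with library 7 as titled, nor did ASV4, ASV10, ASV96 and ASV151 (0.909, 0.832, 0.124 and 0.151). Parasutterella and UCG-009 also missed the threshold without library 1, 3, 8 or 14 (0.0539 to 0.0695), and UCG-009 without library 5 (0.0623). The same holds for ASV97 without library 4, 5, 6, 8, 10 or 12 (0.0512 to 0.0747) and ASV151 without library 1, 2, 3, 5, 8, 10, 11, 12 or 14 (0.0503 to 0.0813).

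Other splits of the same libraries were fitted to see whether they gave as many calls. With 35 splits the smallest share possible is 0.0286, and mice that shared a cage would not be exchangeable between splits. These shares therefore cannot exclude chance. After DSS, 1 of 35 splits, the real one, gave as many ASVs (79, highest other 0) and 1 of 35 as many genera (11, highest other 0). In the GPR15L arm over DSS 1 of 35 gave as many ASVs (80, highest other 1) and 1 of 35 as many genera (8, highest other 0). For the interaction 1 of 100 splits gave as many ASVs (28, highest other 20) and 1 of 100 as many genera (3, highest other 2). Another split thus came close to the real one in both. In the PBS arm 1 of 35 gave as many genera (4, highest other 1). For ASVs in the PBS arm 2 of 35 splits gave as many (12, highest other 13), so another grouping gave more calls than the real one. This other split puts libraries 12, 14 and 15 together. Before DSS, 10 splits are too few for a share under 0.05: for ASVs 1 split gave as many (5, highest other 0) and for genera 10 (0, highest other 1).

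Library 7, which no comparison used, held taxa picked after their values were seen: Parabacteroides at 3.76%, Quinella at 2.94%, Clostridioides at 5.23% and Enterocloster at 0.668%, each above every compared library (highest 2.67% for Parabacteroides, 1.84% for Quinella and 0.166% for Enterocloster). It held 89.3 ASVs at equal depth, with 167329 counts, so low depth is excluded as the reason for its few ASVs. A wrong time point was tested with ASVs marking the times in the other libraries: its score was -0.133, between the libraries before DSS (0.12 to 0.692) and after DSS (-0.833 to -0.295). Whether it belongs to the time before or after DSS therefore cannot be told apart by this test, and a mouse that differed from the others stays open, untested.

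After DSS, 59 ASVs were found in every library of one arm and in none of the other, 18 in the GPR15L arm and 41 in the PBS arm (highest of the other 34 splits 2), but with library 7 as titled, which carried 7 of the 18 and 0 of the 41, only 11 and 0. Depth is excluded: 0 of them had an expected count under 3 in the arm without them (lowest 45.0). For the 41 of the PBS arm, each GPR15L library before DSS carried at least 21 of them, and the PBS libraries before DSS carried 32, 22 and 1. The labels link no mouse or cage between the times, so these numbers cannot exclude a difference already in place before DSS. For the 18 of the GPR15L arm the mean number carried before DSS differed by 1 between the arms (6.67 and 5.67). A difference already in place cannot be excluded there either, as few were found in either arm. Treatment and a shared cage both stay open; no test here separates them.

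Library 6 (PBS before DSS) held 90.6 ASVs at equal depth, the other libraries before DSS at least 163, so depth is excluded. Helicobacter and Mucispirillum took 48.0% of its counts, but without them its mean distance to libraries 4 and 5 was 0.723 (0.732 with them; highest other 0.468), which excludes them as the whole reason. Whether it is a library of the other arm cannot be told apart by distance: it lay at least 0.683 from the GPR15L libraries (at most 0.480 among these), but also 0.721 and 0.742 from libraries 4 and 5 (0.342 between these). A mouse that differed from the others stays open, untested.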

How the results depend on the processing

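The newer quasi-likelihood method and leaving out libraries 6 and 14 together were chosen after the data were seen; the other alternatives were planned. Where no reason is given below, the cause was not tested.

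Of 150 values that answer a comparison under alternatives other than leaving out 1 library, 105 kept their direction and side of the threshold (for counts, lay within 1.5 times), 40 counts moved, 1 value reversed and 4 became weaker. Of 593 values of named taxa, 542 kept both, 49 became weaker, 1 reversed and 1 moved, and of 180 values of lists, held to the unadjusted p, 170 kept both, 3 became weaker and 7 reversed. With 1 library left out, 136 of 196 values that answer a comparison kept both, 40 moved, 14 became weaker, 5 reversed and 1 became stronger, and of 613 values of named taxa 481 kept both and 132 became weaker. Of 420 values of lists 351 kept both, 26 became weaker, 41 reversed and 2 became stronger. With 1 library left out over DSS, the smallest exact permutation p is 0.1 (3 against 3) or 0.0667 (4 against 2). Lists under 0.05 there were thus bound to become weaker or to reverse, and before DSS no list could change side. Library 7 is in neither the comparison before DSS nor that in the GPR15L arm. Values of lists, diversity and distance in these could therefore not change with it as titled. The numbers of lists past the adjustment, 0 throughout, are 12 of the 105 and 28 of the 136 values that kept both and say nothing about stability. A list could pass only where 9 or more of the 15 reached the smallest p together (3 after DSS and 6 in the PBS arm with library 7 as titled), and with 3 against 3 or 4 against 2 libraries none could. Tests of distance and diversity before DSS could not pass either. For diversity only the direction could change. The R2 of distance has no sign, so before DSS it was bound to count among the values that kept both, and says nothing about stability.

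ASVs past the threshold between the arms after DSS (79) became 48 with the filter by mean share, which tests fewer ASVs. Before DSS (5) they became 0 with library 7 as titled, 3 with total counts, 13 with DESeq2, 11 with limma voom, 10 without the filter and 3 with the 2 groups alone. Over DSS in the PBS arm (12) they became 3 with library 7, 47 with DESeq2, 56 with limma voom, 36 without the filter and 53 with the newer method, and in the GPR15L arm (80) 36 with library 7. For the interaction (28) they became 9 with library 7, 52 with DESeq2, 82 with limma voom and 43 without the filter.

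Genera between the arms after DSS (11) became 3 with library 7, 6 with the filter by mean share and 18 with the 2 groups alone, and before DSS (0; 13 at unadjusted p under 0.05 in edgeR) 4 with DESeq2 and 4 with limma voom. In the PBS arm (4) they became 1 with library 7, 13 with DESeq2, 12 with limma voom, 2 with the filter by mean share, 17 with the newer method, 2 without libraries 6 and 14 and 2 with the 2 groups alone. In the GPR15L arm (8) they became 4 with library 7, 14 with DESeq2, 14 with limma voom, 15 with the newer method, 14 without libraries 6 and 14 and 18 with the 2 groups alone. For the interaction (3) they became 0 with library 7, 11 with DESeq2, 12 with limma voom, 6 with the newer method and 1 without libraries 6 and 14. DESeq2 gave no adjusted p for the Clostridia vadinBB60 group, which therefore has no verdict there.

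The Shannon difference over DSS in the PBS arm turned from 0.185 to -0.252 as inverse Simpson index. The Bray-Curtis R2 on genus sums was 0.201 after DSS, 0.263 in the PBS arm and 0.415 in the GPR15L arm, none past the threshold. With library 7 as titled, the R2 on ASVs in the PBS arm went from 0.482 to 0.299 and missed the threshold. With library 7 as titled, ASV15 in the PBS arm turned to 0.72 (log2), and between the arms after DSS Enterobacterales turned to -0.058, Rikenellaceae and Prevotellaceae to 0.12, butyrate-associated Clostridia to 0.22 and sulfate reducers to -0.11, and Gram-positive phyla over DSS in the PBS arm to -0.30. Facultative anaerobes turned to 0.19 after DSS with a pseudocount of 0.001 and to -0.0028 in the GPR15L arm with 0.1.

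With 1 library left out, ASVs past the threshold ranged from 52 to 69 after DSS, 0 to 6 before DSS, 7 to 16 in the PBS arm, 21 to 32 in the GPR15L arm and 17 to 38 for the interaction, and genera from 3 to 11, 0 to 2, 1 to 9, 0 to 3 and 0 to 7. The R2 ranged from 0.451 to 0.646 in the PBS arm and 0.524 to 0.640 in the GPR15L arm; it missed the threshold by construction, since 3 against 3 or 4 against 2 libraries cannot give a p under 0.05. The Shannon difference ranged from -0.234 to 0.592 before DSS and from -0.231 to 0.595 in the PBS arm, and the difference in ASVs at equal depth from -34.9 to -18.1 after DSS, -52.2 to 49.8 before DSS and -56.4 to 45.6 in the PBS arm. Log2 differences of lists that turned sign, none past the threshold, ranged as follows. For lists between the arms after DSS: Facultative anaerobes -0.36 to 0.39, Bacteroides and Parabacteroides -0.20 to 0.66, Sulfate reducers -0.13 to 0.46, Helicobacteraceae and Campylobacterota -0.30 to 0.20. For lists between the arms before DSS: Proteobacteria -0.15 to 1.12, Mucus-associated -2.88 to 0.019, Bacteroides and Parabacteroides -0.71 to 0.43, Rikenellaceae and Prevotellaceae -1.24 to 0.56, Lactobacillaceae and Bifidobacteriaceae -1.58 to 0.34, Sulfate reducers -0.24 to 0.81. For lists over DSS in the PBS arm: Mucus-associated -0.26 to 2.64, Bacteroides and Parabacteroides -0.17 to 0.93, Rikenellaceae and Prevotellaceae -0.58 to 1.22, Butyrate-associated Clostridia -0.55 to 0.10, Lactobacillaceae and Bifidobacteriaceae -0.61 to 1.32, Erysipelotrichales and Turicibacter -0.082 to 3.03, Clostridiaceae and Peptostreptococcaceae -0.94 to 1.98, Sulfate reducers -1.05 to 0.00076, Helicobacteraceae and Campylobacterota -0.58 to 0.13, Gram-positive phyla -0.24 to 0.26, not bacterial -1.14 to 1.13. For lists over DSS in the GPR15L arm: Enterobacterales -0.055 to 0.39, Facultative anaerobes -0.18 to 0.39, Lactobacillaceae and Bifidobacteriaceae -0.073 to 0.17, Helicobacteraceae and Campylobacterota -0.069 to 0.94.

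Depth limits what a count of 0 can exclude: the highest share it allows is 0.00128% in the PBS arm after DSS and 0.000872% in the PBS arm before DSS.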

Other observations

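The values in this part were chosen after the data were seen.

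Before DSS, 8 ASVs were found in all 3 libraries of the GPR15L arm and in none of the PBS arm. After DSS, libraries 8, 9, 10 and 11 of the GPR15L arm carried 0, 1, 1 and 0 of them, and libraries 12, 13, 14 and 15 of the PBS arm 4, 4, 3 and 5. Library 7 carried 0. The 1 ASV found in all 3 libraries of the PBS arm and in none of the GPR15L arm before DSS was found in all 8 libraries after DSS.

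Of the 41 ASVs found after DSS in every PBS library and no GPR15L library, libraries 1, 2 and 3 carried 27, 21 and 22, libraries 4, 5 and 6 carried 32, 22 and 1, and library 7 carried 0. Libraries 6 and 7 shared 74 ASVs, at a Bray-Curtis distance of 0.547. Library 7 lay at a mean distance of 0.586 from the GPR15L arm before DSS, 0.577 from the PBS arm before DSS and 0.729 from the PBS arm after DSS, and at 0.562 to 0.641 from the libraries of the GPR15L arm after DSS.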
